A study of Schmidtea mediterranea with 9 samples.

How the data were processed

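The study measured gene expression in single stem cells of the planarian flatworm *Schmidtea mediterranea*, strain CIW4. Animals were taken apart into single cells, 10 animals for each biological replicate, and live cells with replicated DNA (the X1 gate, which is rich in the pluripotent stem cells called neoblasts) were sorted for droplet-based 3' RNA sequencing with 10x Genomics reagents, per the labels' protocols. DASH is the removal of an abundant sequence from a cDNA library with Cas9. Per the labels' protocols, 30 guide RNAs against mitochondrial 16S rRNA were used at 300 nM with 30 nM Cas9 on 1 ng of cDNA, followed by 10 cycles of PCR, and untreated libraries had neither step. Digestion and the added PCR therefore cannot be separated in the comparison of DASHed with untreated libraries.

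The deposited files are sparse matrices of UMI counts per feature and cell barcode, which are raw whole numbers with no normalization. They were made with Cell Ranger 6.1.2, per the submitters' processing notes. Per the file headers, Cell Ranger 6.1.2 made the 6 matrices of untreated and DASHed libraries, and Cell Ranger 4 the 3 matrices labelled noPCR, 5cycles and 10cycles. The genome build, the annotation and the number of reads per library are not given in the sources used here. The 6 untreated and DASHed matrices held cell barcodes only, each with at least 500 UMIs, and the 3 other matrices held between 521683 and 613902 barcodes each, most of them without a cell. All 9 libraries list the same 22029 features. Of these, 14 carry names and are mitochondrially encoded, and 22015 are identifiers that the files do not pair with gene names. The 16S feature was taken by its name. The planned nuclear gene lists and cell type markers could therefore not be matched, the mitochondrially encoded list (13 features, 16S left out) was the only list tested, and clusters stay numbered and unnamed.

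Libraries were grouped by their labels into untreated (n = 3), DASHed (n = 3) and 1 library each labelled noPCR, 5cycles and 10cycles. For untreated against DASHed, a single value per library (16S share, median UMIs and genes per cell, share of cells per cluster) was compared with an exact two-sided permutation test, which cannot go below p = 0.1 for 3 against 3 libraries. Genes per cell were counted without 16S. For genes at equal depth, each cell was thinned without replacement to 2000 UMIs and shallower cells were left out. Counts summed per library were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. DESeq2 1.42.0 was the alternative. The gene list was tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry from limma 3.58.1. CPM values are scaled to the UMIs outside 16S. The standard error of an edgeR log2 fold change was taken as its size divided by the square root of the test's F.

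Same-numbered untreated and DASHed libraries share replicate numbers in the labels. After the group means were removed, log2 CPM of same-numbered libraries over 7987 features correlated at 0.966, 0.957 and 0.967, and 79.4% to 98.9% of their barcodes were the same against at most 0.21% for other numbers. The numbers were therefore taken to pair the libraries. The fit without the pairs is the one fixed in the plan, and the fit with the replicate number as a block is given where it changes a call. Because paired libraries hold mostly the same cells, the blocked fit measures reproducible differences between paired libraries. Its sums run over all listed barcodes, and 378, 771 and 1266 untreated barcodes were not listed in the paired DASHed library. Differences between the cell lists therefore enter it beside differences between treatments of the same cDNA.

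For clusters, cells with at least 200 genes from the 6 libraries were pooled without 16S (Scanpy 1.11.5: scaling to 10000 UMIs, log transform, 2000 variable genes, 30 principal components, 15 neighbours; Leiden at resolution 0.6 with python-igraph 0.11.9) without batch integration. Clusters with at least 50 cells in every library were tested. Scrublet marked 13 of 23777 cells (0.0547%) as doublets, too few for the caller to have worked, so doublets were in effect not removed. In the 3 unfiltered libraries, cells were barcodes with at least the 99th percentile of UMIs among the 4000 barcodes with the most UMIs divided by 10. With 1 library per group no test was made there, and exact 95% intervals (Clopper-Pearson for shares, Poisson for counts) cover counting error only.

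Features named in the text followed a rule fixed before the data were examined. It took all mitochondrially encoded features. Of the features past the threshold with the same sign in all 3 pairs, it took those with the largest fold changes. For the 3 cycle libraries it took those with the largest and smallest ratio of 10cycles to noPCR. That ratio was limited to features with at least 500 UMIs summed over the cells of the 3. As the fit without pairs called no feature, the rule was applied to the blocked fit, a choice made after seeing the data. At most 2 unnamed identifiers are given in each direction.

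The edgeR procedure was tested on simulated data with 200 changed genes among 15621, drawn from the means and library sizes of DASHed against untreated. All genes had the same dispersion (spread beyond counting error), the common one of the blocked fit. Unchanged genes had equal mean shares in paired libraries. The simulated data thus followed the blocked fit by construction. Its recovery and false calls there cannot check its calls in the real data. The blocked fit recovered 60% of 1.25-fold, 74% of 1.5-fold, 86% of 2-fold and 98% of 4-fold changes and called 7 unchanged genes. Without the block it recovered 0% of 1.25-fold and 1.5-fold, 20% of 2-fold and 70% of 4-fold changes. Alternatives covered left-out libraries, scaling, filters, thinning, barcode sets, doublets, cluster resolution and cell definitions. Alternatives of the blocked fit, fits of the list on shared barcodes, thinning outside 16S on shared barcodes and clustering without the called features were chosen after seeing the data. So was the sign-flip test of the 16S share by cluster.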

Results

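Single-cell libraries of sorted planarian stem cells were examined before and after DASH, to assess what removal of mitochondrial 16S rRNA does to them. The 3 untreated libraries held 4288, 4613 and 6140 cell barcodes with 65585661, 44443793 and 59207042 UMIs. The 3 DASHed libraries held 4002, 3885 and 4952 cell barcodes with 27753279, 20158771 and 23528810 UMIs. A further 3 libraries, labelled noPCR, 5cycles and 10cycles, held 13806636, 20145705 and 23318526 UMIs over all barcodes.

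The first comparison asked how much 16S rRNA, the RNA of the large subunit of the mitochondrial ribosome, remained after DASH. 16S took 69.7% ± 3.74 of UMIs (SD, n = 3) in untreated libraries and 0.0252% ± 0.0279 (SD, n = 3) in DASHed libraries. The untreated shares were 65.7%, 70.4% and 73.0%, and the DASHed shares of the same replicates 0.00698%, 0.0573% and 0.0113%. Wilson score 95% intervals of these DASHed shares were 0.00668% to 0.00730%, 0.0563% to 0.0584% and 0.0109% to 0.0118%. The share fell 9409-fold, 1229-fold and 6439-fold in the 3 same-numbered pairs. No library of either group overlapped the other (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries allow). DASHed replicate 2 held most of what was left, and without it the DASHed mean was 0.00916%. In DASHed replicates 1, 2 and 3, 65.6%, 14.7% and 61.9% of barcodes had no 16S UMI, against 0% of untreated barcodes.

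**Figure D1:**
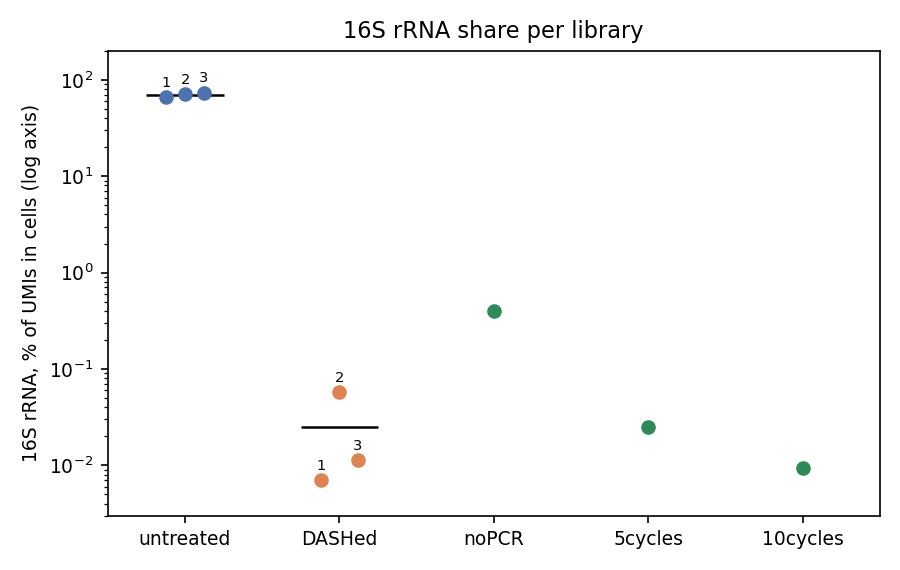
Percent of UMIs on 16S rRNA in cell barcodes of each library, on a log axis. Points are libraries (numbers give the replicate), lines are means of 3 libraries, and the libraries labelled noPCR, 5cycles and 10cycles are single; untreated libraries lie between 65.7% and 73.0% and all others below 1%.

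The 16S share differed between untreated barcodes. In untreated replicates 1, 2 and 3, 474, 952 and 1840 barcodes (11.1%, 20.6% and 30.0%) had at least 90% of their UMIs on 16S. The limit of 90% was chosen after the distribution was seen, and 296, 454 and 863 barcodes lay between 85% and 95%. These barcodes had a median of 30.7 ± 9.61 genes (SD, n = 3), against 1717 ± 314 in the other barcodes. Outside 16S, the other mitochondrially encoded features took 77.6% ± 0.900 of their UMIs, against 5.91% ± 0.122 in the other barcodes. 12S rRNA, the RNA of the small mitochondrial ribosomal subunit, alone took 21.5% ± 2.98 against 0.602% ± 0.0843 (SD, n = 3). Of these barcodes, 38.6%, 30.6% and 39.1% were also listed in the DASHed library of the same number.

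**Figure D2:**
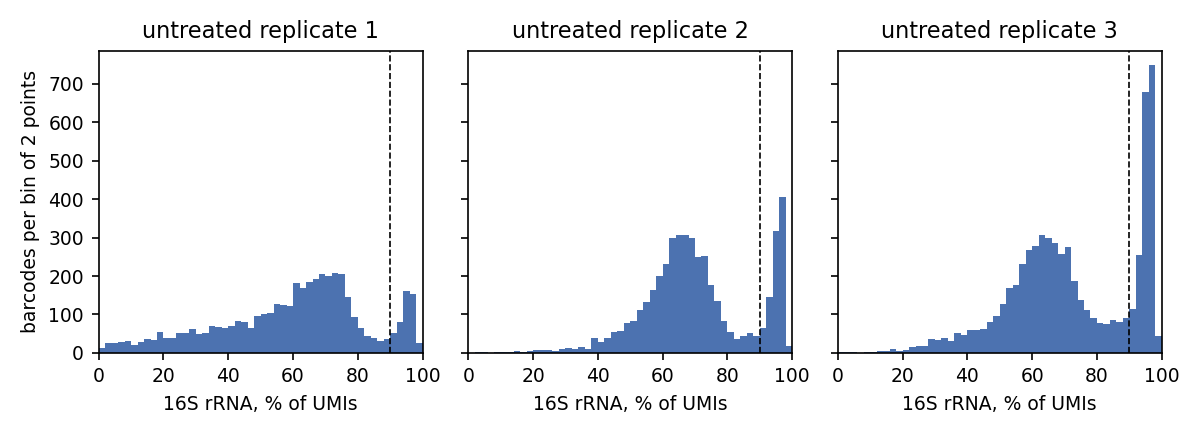
Number of cell barcodes by percent of UMIs on 16S rRNA in the 3 untreated libraries, in bins of 2 percentage points; the dashed line marks 90%. Barcodes to its right number 474, 952 and 1840.

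The next comparison asked what the libraries held outside 16S. Median UMIs per cell outside 16S were 3028 ± 1207 in untreated and 4861 ± 868 in DASHed libraries (SD, n = 3), higher in 3 of 3 pairs by 1833 ± 346 (SD of the 3 differences; exact permutation test, two-sided p = 0.2). Median genes per cell were 1475 ± 414 in untreated and 2076 ± 235 in DASHed libraries (n = 3), higher in 3 of 3 pairs by 600.3 ± 182 (exact permutation test, two-sided p = 0.2). The permutation test ignores the pairs; the exact sign-flip test of the 3 paired differences gave p = 0.25 for each, the smallest that 3 pairs allow. Total UMIs outside 16S were 1.23, 1.53 and 1.47 times those of the untreated library of the same number, while total UMIs were 0.423, 0.454 and 0.397 times. The number of reads behind each library is not given in the sources used here.

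Between 79.4% and 91.2% of untreated barcodes and between 97.7% and 98.9% of DASHed barcodes were found in the same-numbered library of the other group. On these shared barcodes the median ratio of DASHed to untreated was 1.46 ± 0.186 for UMIs outside 16S and 1.27 ± 0.106 for genes (SD, n = 3). Barcodes listed only in untreated libraries numbered 378, 771 and 1266 and had medians of 43.5, 21 and 38 genes.

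When each cell was thinned to 2000 UMIs in total, untreated cells had 469 ± 39.7 genes and DASHed cells 1153 ± 3.61 (SD, n = 3; exact permutation test, two-sided p = 0.1, the smallest possible). The draw included 16S UMIs, and 16S is not counted as a gene. The gap therefore follows largely from the 16S share and is no separate result. Thinning to 2000 UMIs in total left out 158, 42 and 81 untreated and 475, 487 and 1069 DASHed cells. When each cell was thinned to 2000 UMIs outside 16S, untreated cells had 1154 ± 8.39 genes and DASHed cells 1153 ± 3.79, a mean difference of -1.67 ± 4.62 genes over the 3 pairs (exact permutation test, two-sided p = 1). This left out 884, 1815 and 2889 untreated and 475, 489 and 1069 DASHed cells.

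**Figure D3:**
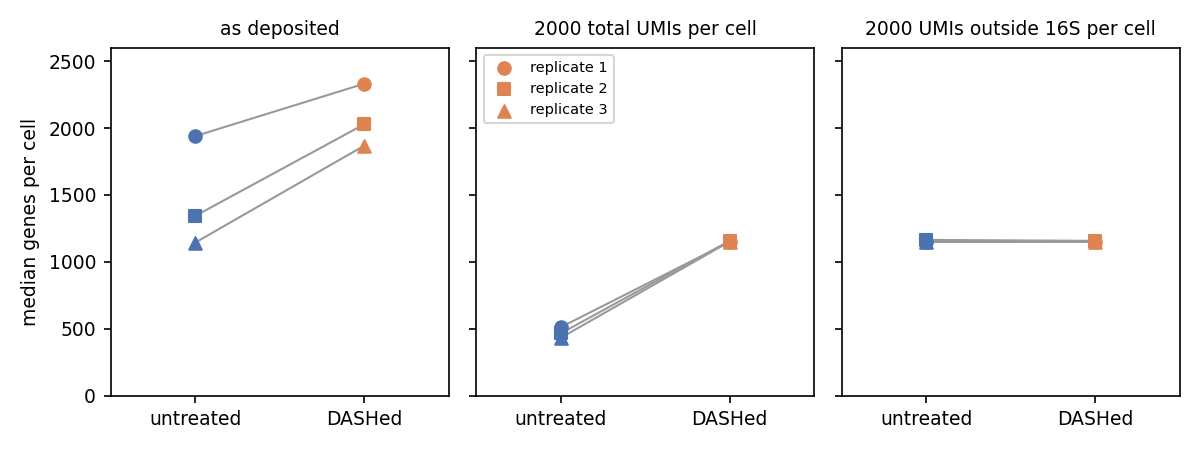
Median genes per cell in same-numbered untreated and DASHed libraries (joined points), as deposited, after thinning to 2000 UMIs in total, and after thinning to 2000 UMIs outside 16S. The rise from 1475 to 2076 and from 469 to 1153 genes gives way to 1154 and 1153 genes in the last panel.

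The comparison of summed counts asked which other features differed after DASH. In the planned edgeR fit no feature passed an adjusted p of 0.05, 16S included (log2 fold change -13.20 ± 1.81 SE, adjusted p = 0.154). The same fit gave 828 of 16229 features at an unadjusted p under 0.05, and DESeq2, also without the block, called 162, among them 16S (log2 fold change -13.22, adjusted p = 2.01e-40). Without untreated replicate 1 the edgeR fit called 12 features, and without DASHed replicate 1 it called 4. With the replicate number as a block, edgeR called 1380 features higher and 1190 lower in DASHed libraries. In the blocked fit 16S fell by 13.82 ± 0.70 SE on the log2 scale (adjusted p = 1.8e-05). Most other changes were small: 91.2% of features lay within 0.5 on the log2 scale, and the median size of the called changes was 0.33. Without replicate 3 the blocked fit called 1207 features, and with a minimum change of 0.5 it called 879.

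Of the 13 other mitochondrially encoded features, 12 were lower in DASHed libraries in the blocked fit with TMM scaling, and all 13 were higher under scaling to total counts, which moved the median of all features to 1.74. Relative to the median of all features, 12 of the 13 lay lower under either scaling. The median of the list minus that of all features was -0.25 with TMM and -0.24 with total counts. A change of scaling moves all features by nearly the same amount, so this match between scalings could hardly have come out otherwise. The 12 were also called when adjusted over the list alone, and the fit without the block called 0 of 13 by either adjustment. nd3, a subunit of respiratory complex I, was 10565 ± 1033 CPM in untreated and 7128 ± 761 CPM in DASHed libraries, a blocked log2 fold change of -0.60 ± 0.05 SE (edgeR adjusted p = 0.000188). nd4, of the same complex, had -0.38 ± 0.04 SE, and cox3, a subunit of cytochrome c oxidase, -0.32 ± 0.02 SE. 12S rRNA had -0.31 ± 0.02 SE, and ATP6, a subunit of ATP synthase, -0.13 ± 0.01 SE. All these values run over all listed barcodes, those listed only in untreated libraries included. On barcodes shared by same-numbered libraries, given below, neither 12S rRNA nor ATP6 was called. nd2 was not called (log2 fold change 0.00 ± 0.08 SE).

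As a list, the 13 features had a median log2 fold change of -0.26 without the block (camera p = 1.63e-08 with the preset correlation, p = 0.128 with an estimated correlation, fry p = 0.177). With the block the median was -0.25 (camera p = 2.76e-14, p = 0.0698 with an estimated correlation, fry p = 0.00712). Without untreated replicate 3 the median was -0.10, and without DASHed replicate 3 it was -0.39. On barcodes shared by same-numbered libraries, the blocked median was -0.08 and 7 of 13 features were called lower. Without the block, camera with an estimated correlation gave p = 0.342 on these barcodes and fry p = 0.424. With the block, camera gave p = 1.17e-05 with the preset and p = 0.0435 with an estimated correlation, and fry p = 0.00893. There, 12S rRNA had -0.05 ± 0.02 SE (edgeR adjusted p = 0.206), ATP6 0.05 ± 0.03 SE (adjusted p = 0.370), and nd3 -0.45 ± 0.03 SE (adjusted p = 0.000156).

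**Figure D4:**
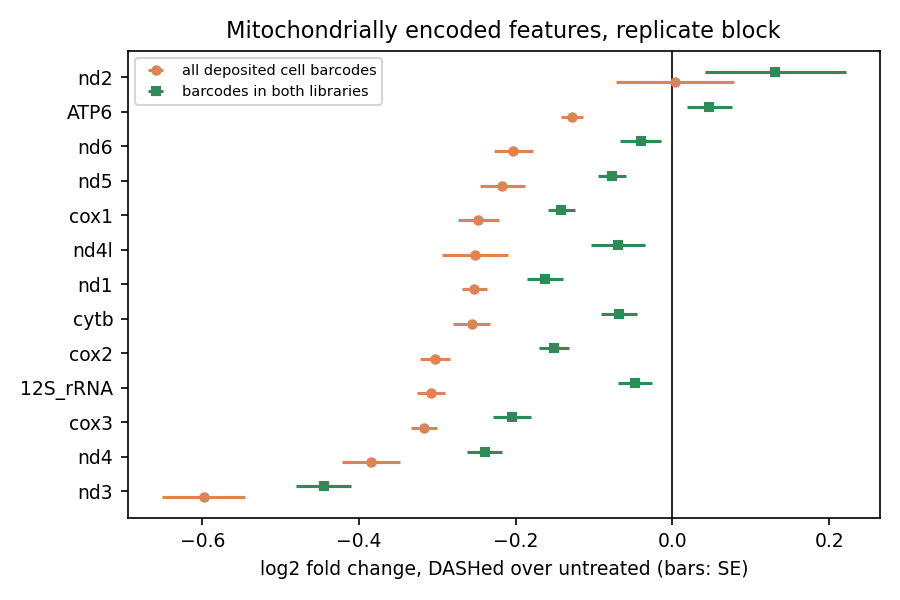
Log2 fold change (DASHed over untreated, edgeR with replicate block and TMM scaling, bars SE, 3 pairs) of 13 mitochondrially encoded features over all cell barcodes and over barcodes found in both libraries. The median moves from -0.25 to -0.08, and under scaling to total counts, not drawn, all 13 lie above 0 but 12 lie below the median of all features, 1.74.

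Among nuclear features, 1380 were called higher and 1177 lower in the blocked fit with TMM scaling. The balance depends on the scaling: over all features, the blocked fit called 1274 higher and 1609 lower with the size factors of DESeq2, and 16163 higher and 8 lower with total counts. SMESG000006000.1 had the largest fall, from 50.2 ± 7.39 to 8.67 ± 2.68 CPM (SD, n = 3). SMESG000018945.1 had the largest rise, from 0.122 ± 0.0318 to 0.567 ± 0.205 CPM. That rise lies near the floor: replicate 1 held 2 UMIs of it in the untreated and 11 in the DASHed library. SMESG000071531.1, chosen for its ratio between the cycle libraries below, had a blocked log2 fold change of 1.48 ± 0.16 SE (edgeR adjusted p = 0.000441).

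Clustering asked whether removal of 16S reached all groups of cells and whether it changed their shares. The 23777 cells formed 20 clusters, of which 8 had at least 50 cells in every library. In these 8, the untreated 16S share ran from 46.5% ± 2.22 in cluster 9 to 67.3% ± 1.48 in cluster 4 (SD, n = 3), and the highest DASHed share in any library was 0.0547%. Each of the 8 clusters had an exact permutation p of 0.1, the smallest possible (adjusted p = 0.1). Cluster 8, too small in some libraries to be tested, had an untreated 16S share of 85.3% ± 3.25 and a median of 537 ± 109 genes. Its mean DASHed 16S share was 0.0795% ± 0.0950 (SD, n = 3), against means of 0.0141% to 0.0240% in the 8 tested clusters. Untested clusters with cells in every library ran from 0.0110% in cluster 11 to this value. Cluster 8 made up 4.33% ± 2.85 of untreated and 2.63% ± 1.71 of DASHed cells, lower in 3 of 3 pairs (exact permutation test, p = 0.4, adjusted p = 1).

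Cluster shares cover only cells with at least 200 genes. The untreated barcodes at or above the 16S limit set earlier had a median of 30.7 ± 9.61 genes (SD, n = 3). Most of them were therefore left out, and a difference in their number between the cell lists hardly enters these shares. Among the clustered cells, the largest difference between groups in a cluster's share was 1.70 percentage points. The mean cluster make-up of the groups differed by 3.20 percentage points (total variation distance; exact permutation test, p = 0.7, and p = 0.25, the smallest possible, with labels exchanged within pairs). The lowest adjusted p of a single cluster was 1, but 3 libraries against 3 cannot go below an exact p of 0.1, so this test could call no cluster. Same-numbered libraries differed by 1.40 to 5.01 points, and libraries of other numbers by 10.5 to 33.2 points. Leaving out a library raised the distance between groups to between 5.97 points (without DASHed replicate 2) and 11.2 points (without untreated replicate 1), where the groups no longer held the same 3 numbers. Clustering without the features called in the blocked fit gave 3.18 points. Of the 3735, 3594 and 4217 barcodes that had at least 200 genes in both same-numbered libraries, 91.5% ± 4.30 (SD, n = 3) fell into the same cluster, against 10.9% to 12.2% by chance.

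Within the 8 tested clusters, edgeR called 23 features higher and 119 lower without the block, summed over clusters, and 16S was among the lower ones in all 8. 16S was called in 5 of the 8 without untreated replicate 2, in 6 without untreated replicate 3 and in 4 without DASHed replicate 3, and in all 8 without any other single library and with the block. With the block it called 2116 higher and 1896 lower. The count without the block was 226 without untreated replicate 1, 37 without untreated replicate 2, 34 without untreated replicate 3, 305 without DASHed replicate 1, 42 without DASHed replicate 2 and 27 without DASHed replicate 3.

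The last comparison set the libraries labelled noPCR, 5cycles and 10cycles side by side, 1 library each, so that no difference has a replicate check. Their cells numbered 3443, 3411 and 3413, and 99.3%, 99.1% and 99.1% of their barcodes were in untreated replicate 1. 16S took 0.395% (exact 95% interval 0.392% to 0.399%) of UMIs in cells of the library labelled noPCR, 0.0248% (0.0241% to 0.0255%) in 5cycles and 0.00928% (0.00888% to 0.00970%) in 10cycles. The share in noPCR was 42.6 times that in 10cycles (40.7 to 44.6). Untreated replicate 1 had 65.7% and DASHed replicate 1 had 0.00698%. Median genes per cell were 1503, 2015 and 2206 as deposited, and 674, 680 and 680 when each cell was thinned to 1000 UMIs, against 290 in untreated replicate 1 and 677 in DASHed replicate 1.

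nd3 stood at 8148 CPM (exact Poisson interval 8098 to 8198) in noPCR, 3983 CPM (3954 to 4011) in 5cycles and 4758 CPM (4729 to 4787) in 10cycles. cox3 stood at 5235, 4158 and 4230 CPM, and ATP6 at 14388, 16121 and 16027 CPM. Untreated replicate 1 had 10176, 5539 and 18245 CPM of nd3, cox3 and ATP6. DASHed replicate 1, also with 10 added cycles per the protocol, had 7776, 4429 and 16643 CPM. The values of untreated and DASHed replicate 1 run over all their listed barcodes, not over cells above the UMI limit used for the 3 single libraries. Ratios of 10cycles to noPCR were taken for 8022 features with at least 500 UMIs summed over the cells of the 3 libraries. Of these, 95.4% lay within 1.5 times, 63 were under 0.5 and 29 above 2. SMESG000006000.1 had the smallest ratio, 0.209, with 48.6 CPM in noPCR, 6.25 in 5cycles and 10.2 in 10cycles, beside 46.6 in untreated and 11.6 in DASHed replicate 1. SMESG000071531.1 had the largest, 4.51, with 131 CPM in noPCR, 265 in 5cycles and 592 in 10cycles, beside 120.1 in untreated and 276 in DASHed replicate 1.

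Nuclear features called in the blocked fit of replicates 2 and 3 alone were followed in replicate 1, on barcodes shared by its libraries, a comparison chosen after seeing the data and limited to features with at least 50 UMIs per library on average over untreated and DASHed replicate 1. The 1104 features called lower had a median log2 ratio of -0.14 for DASHed over untreated replicate 1, 0.00 for noPCR over untreated replicate 1, -0.24 for 5cycles over noPCR and 0.01 for 10cycles over 5cycles; DASHed over 10cycles gave 0.11. For the 1013 features called higher these medians were 0.32, -0.10, 0.26, 0.07 and 0.05. The 10270 features past this minimum that were not called had -0.01, -0.02, 0.03, -0.01 and -0.02. The same check of DASHed over untreated gave -0.29 and 0.27 for features called lower and higher when replicate 2 was the one left out of the fit, and -0.56 and 0.41 for replicate 3.

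**Figure D5:**
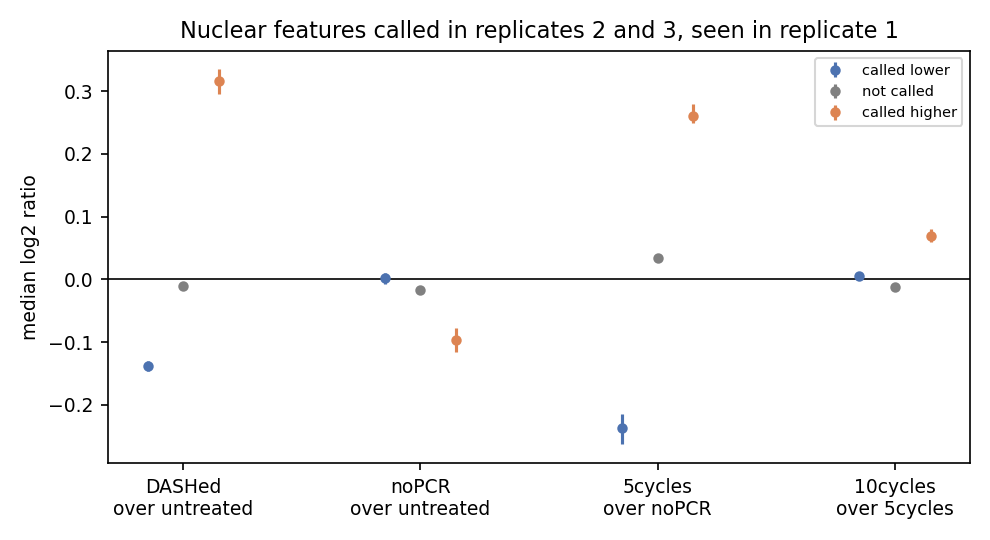
Median log2 ratio (bars: bootstrap 95% interval over features) between libraries of replicate 1 for nuclear features called lower, not called or called higher in replicates 2 and 3. The medians of called features lie at 0.00 and -0.10 for noPCR over untreated, at -0.24 and 0.26 for 5cycles over noPCR, and at 0.01 and 0.07 for 10cycles over 5cycles.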

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

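The tests on barcodes below the cell limit and on barcodes dominated by 16S were chosen after the results were seen, as was the use of the planned thinned and shared-barcode values to weigh explanations. 16S was also counted outside the main measurement, in barcodes below the cell limit of the 3 unfiltered libraries; these values are listed because they exceed the limit of a count of 0, which nearly any count passes. 16S took 2.30% of UMIs in such barcodes of the library labelled noPCR (95% interval 2.27% to 2.32%), against 0.395% in its cells. In 5cycles it took 0.104% (0.0992% to 0.109%) against 0.0248%, and in 10cycles 0.0363% (0.0336% to 0.0392%) against 0.00928%. The other mitochondrial features moved with it, with 23.3%, 27.9% and 27.5% of UMIs outside 16S in these barcodes against 5.46%, 5.00% and 5.11% in cells. Of the 474 barcodes of untreated replicate 1 with at least 90% 16S, 466, 468 and 468 fell below the cell limit and held 23.1%, 37.5% and 33.9% of the 16S UMIs there; without them the 16S share was 2.01%, 0.0750% and 0.0276%. Each library is single, and no untreated library was analysed with its empty barcodes here.

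Another pattern is the set of untreated barcodes with at least 90% of UMIs on 16S. Free RNA spread evenly over droplets does not account for them in replicate 1: in the 3 unfiltered libraries the other mitochondrial features took 75.1%, 82.3% and 81.1% of their UMIs outside 16S, against 20.3%, 24.3% and 24.0% in barcodes outside the cell lists, where evenly spread RNA would give the same composition. Ordinary cells whose UMIs were taken up by 16S are also argued against, since those also listed in DASHed libraries still had a median of 36.5 ± 9.99 genes there, against 2206 ± 192 in the other shared barcodes (SD, n = 3). The 77.6% of UMIs outside 16S that fell on other mitochondrial features, against 5.91% elsewhere, is consistent with barcodes that hold mostly mitochondrial RNA. Whether these are mitochondria released from cells or damaged cells stays open, either would have to arise after the sort for live cells with replicated DNA or pass it, and no biological explanation was tested, since no group of the design bears on it.

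The rise in genes per cell in DASHed libraries was also weighed. The absence of 16S-dominated barcodes from the DASHed cell lists cannot be its whole cause, since the difference on shared barcodes was still 436 ± 114 genes (SD over 3 pairs) against 600.3 ± 182 on all barcodes. A gain in UMIs outside 16S per cell is a candidate explanation for the rest: at 2000 UMIs outside 16S the difference was -1.67 ± 4.62 genes. Reads per library are not given, so how much of the gain came from deeper sequencing stays open.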

How the results depend on the processing

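Of 114 alternatives over 11 results, 80 were counted as unchanged, by rules that differed between results. Counts of called features had to stay of similar size, and the ratio of noPCR to 10cycles within its main interval. The other results had to keep the direction and the side of the threshold or move less than the spread between replicates. Some of the 80 could not move: sign-flip and label-exchange tests repeat the main value, and a minimum change leaves 0 calls at 0. The count of 80 is therefore not a measure of stability. The cause of the changes in the other alternatives was not tested unless stated. The 16S share kept its difference between -71.7 and -68.0 percentage points when single libraries were left out. The difference in median UMIs per cell outside 16S (1833) was 1459 on shared barcodes, 1405 in cells with at least 500 UMIs outside 16S, and 1343 to 2523 without single libraries. The difference in genes per cell (600.3) was 286 when a gene needed at least 2 UMIs, while the mean ratio went from 1.45 to 1.72, and 434 to 832 without single libraries. At a fixed depth it was 412 genes at 1000 and 1070.5 at 4000 total UMIs, and it turned to -1.67 at 2000 UMIs outside 16S and to -1.33 on shared barcodes, within the spread of the pairs. With the replicate block the calls in summed counts went from 0 to 2570, within clusters from 142 to 4012, and in the mitochondrial list from 0 to 12 of 13 features, with a fry p of 0.00712 in place of 0.177. It changed no other call, but the exact sign-flip tests of the other results cannot go below p = 0.25, so they say nothing about stability. DESeq2 called 162 features. Scaling to total counts called 15116 features without and 16171 with the block, as it spreads the loss of 16S over all features. Leaving out single libraries gave 0 to 12 calls in summed counts and 27 to 305 within clusters, and leaving out whole same-numbered pairs gave 1207 to 2314 with the block. A minimum log2 change of 0.5 left 879 blocked calls, by construction. The mitochondrial list (median -0.26) lost its camera call with an estimated correlation (median -0.26, p = 0.128), and its median ran from -0.39 to -0.10 without single libraries. On shared barcodes the blocked median was -0.08 and 7 of 13 features were called lower. There, camera with an estimated correlation gave p = 0.0435 with the block and p = 0.342 without it. The distance in cluster make-up among cells with at least 200 genes (3.20 points) ran from 5.97 to 11.2 points without single libraries. The ratio of noPCR to 10cycles in 16S share (42.6) was 49.5 over all barcodes. Alternatives of the blocked fit, list fits on shared barcodes, thinning outside 16S on shared barcodes and clustering without called features were chosen after seeing the data. So was the sign-flip test of the 16S share by cluster. Depth limits the thinned values, which leave out shallow cells, and the DASHed 16S share, which rests on 1937 to 11560 UMIs per library.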

Other observations

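The tests of explanations and the comparisons with other splits were chosen after the results were seen; the calls and the camera p of the real split were planned. Clusters of untreated cells differed in the share of the other mitochondrial features. Cluster 5 had 2.23% ± 0.494 of UMIs outside 16S on these features and a 16S share of 57.5% ± 3.92, and cluster 4 had 7.55% ± 1.41 and 67.3% ± 1.48. The untested clusters 8 and 10 had 22.5% ± 10.6 and 16.3% ± 1.84, with 16S shares of 85.3% ± 3.25 and 79.0% ± 2.61 (SD, n = 3). A relation between these shares across clusters was not tested.

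A hypothesis for the features that differed in the blocked fit is that the added PCR cycles moved them. In replicate 1 the median log2 ratio of 10cycles over noPCR was 0.36 for features called higher and that of 10cycles over 5cycles 0.07, so that added cycles may account for part of the rise. For features called lower it was -0.24, but 10cycles over 5cycles gave 0.01, so that 5 further cycles did not lower them and an effect of cycles cannot be told apart from another difference between noPCR and 5cycles; DASHed over 10cycles gave 0.11 for them. Cutting of other cDNA by Cas9 also stays open with 1 library without added cycles: noPCR over untreated replicate 1 had a median of 0.00 (0.00213, bootstrap 95% interval -0.01 to 0.01) for features called lower and -0.10 (-0.12 to -0.08) for those called higher. The labels do not state that these single libraries were digested. Their 16S shares in cells were 0.395%, 0.0248% and 0.00928%, against 65.7% in untreated replicate 1, which argues against libraries left undigested. The file headers name another Cell Ranger version for them. No biological explanation was tested, since paired libraries share most of their cells.

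Other splits of the libraries were run for each fit. The 10 splits of the 6 libraries into 3 and 3, and the 4 of them that part all 3 pairs, are too few for a share under 0.05. In summed counts without the block the real split gave 0 calls and the highest other split 0, so that all 10 gave as many. With the block the real split gave 2570 calls and the highest of the other splits that part all 3 pairs 0, with 1 split as large. For the mitochondrial list the real camera p was 1.63e-08 and the smallest other p was 4.26e-09, with 2 of the 10 splits as small, but that split parts only 1 pair, and among splits that part all 3 pairs the smallest other p was 6.99e-05. Within clusters the real split gave 142 calls and the highest other 830, with 2 of the 10 splits as large. The split with 830 calls also parts only 1 pair, and why it gave so many calls was not identified. The other splits that part 1 pair gave 0 or 1 calls, and the other splits that part all 3 pairs gave 0. With the block the real split gave 4012 calls within clusters and the highest other 3, with 1 as large.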
